A study of Ciona robusta with 15 samples.

How the data were processed

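Polyadenylated RNA of the oral siphon of Ciona robusta, a solitary sea squirt, was sequenced in 15 libraries. Per the labels' protocols, the animals were siblings about 6 months old raised from the gametes of a pair of adults, and each library was made from the pooled RNA of 5 siphon samples and read on an Ion Proton instrument. The libraries fall into 5 groups of 3, taken from the labels: non-regenerating siphons, and siphons 0, 1, 3 and 8 days after amputation, of which the first were taken at once. Each library is therefore a separate pool of tissue, and its values carry the average of that pool and not the spread between animals. The labels do not say whether the pools shared animals, which animals were housed together, or how the non-regenerating siphons differed from those of day 0 in handling.

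The values deposited by the authors are raw read counts per Ensembl transcript identifier, with no normalization. The submitters' processing notes name TopHat, Bowtie and HTSeq. The versions, roles and settings of these tools, the genome build, the annotation release and the use of strand are not given in the sources used here. The table holds 17745 transcript identifiers, of which 69 had no count in any library. Of the 17745 identifiers, 0 were found in the reference table of 21486 genes used here, so they could not be paired with gene names. The lists of genes by pathway and cell type that had been drawn up could therefore not be tested, and transcripts are given by identifier, without positions.

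Depth ran from 7039611 counts in day 3 replicate 1 to 33413013 in non-regenerating replicate 2. With edgeR's default minimum count of 10 in its expression filter, 15328 transcripts were tested and 2417 were dropped; the tested ones held at least 99.95% of the counts of each library. Counts are read counts and not molecules, so counting intervals cover counting error only. Counts of 105 sets of transcripts, 214 in all, agreed within 1% of their totals (sets of at least 100 counts), as happens when reads are shared between copies or isoforms, and such transcripts were also counted once as an alternative. None of the transcripts named in the text, each of which was checked, belongs to such a set. The 1% rule cannot catch transcripts that move together at different levels. ENSCINT00000002977 and ENSCINT00000002984 did so, with 2549 and 2814 counts in day 0 replicate 1 and 856 and 961 in day 1 replicate 1. Whether they share reads was not tested, and they may be a single signal. Overlapping and antisense transcripts could not be told apart, because strand use is not given. No replicate pair agreed within sampling noise, and every library was counted as 1 replicate.

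Counts were scaled with the trimmed mean of M-values (TMM) in edgeR 4.0.16 under R 4.3.3. A negative binomial quasi-likelihood model with a mean per group was fitted to all 15 libraries together (glmQLFit with robust estimation, then glmQLFTest), so that all groups share an estimate of the spread. P-values were two-sided and were adjusted by the Benjamini-Hochberg method over the 15328 transcripts of each comparison, with a threshold of 0.05 and no minimum fold. The standard error of a log2 fold change was computed from the fold change and its F statistic. Levels are in CPM, the usual unit of counts scaled to a common library total; they are TMM-scaled unless the text says that they are of the library total, and are given as mean ± SD. Log2 CPM for the principal components and correlations used a prior count of 0.5. Replicate numbers recur in every group; whether they pair the samples was checked, and the block fit is given with the other alternatives.

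Days 1, 3 and 8 were each compared with day 0 and, as another reference, with the non-regenerating group. The non-regenerating group was compared with day 0, day 3 with day 1 and day 8 with day 3; the contrast of day 8 with day 1 was not planned. An F-test over the 5 groups asked which transcripts differed between any of them. A comparison of the mean of days 1, 3 and 8 with day 0 was added after the data were seen. In each comparison the named transcripts were, by rule, at most 2 with the largest rise and 2 with the largest fall in log2 fold change among transcripts past the threshold, with no overlap in CPM between the libraries of the groups and a mean of at least 5 CPM in the higher group. Where no transcript passed, the 2 in each direction with the lowest p and the same minimum mean were chosen after their values were seen. ENSCINT00000024202, which completes a count of 5 calls, and the very abundant ENSCINT00000009238 and ENSCINT00000019271 were also chosen after their values were seen.

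The comparisons, the naming rule and the following alternatives were fixed before the data were examined. The alternatives were size factors as in DESeq2, library totals alone, no filter beyond a single count, a filter of at least 10 CPM in 3 libraries, DESeq2 1.42.0, limma voom (limma 3.58.1), the replicate number as a block, only the 6 libraries compared, library sizes without the 20 most counted transcripts, another reference group, and each library left out in turn. Library weights in limma voom, the fit without the non-regenerating group, thinning to the smallest library, counting near-identical transcripts once, and leaving out the libraries numbered 3 were added after the data were seen.

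The test was checked on simulated counts with the mean of each transcript over all libraries and with the depths and dispersions estimated here, in which 200 of 15328 transcripts, with a mean of at least 1 CPM, were changed. For day 1 against day 0, it recovered 7 of 50 transcripts changed 2-fold, 33 of 50 changed 4-fold, 46 of 50 changed 8-fold and 48 of 50 changed 16-fold, with 8 false calls among 142. For day 8 against day 0 it recovered 5 of 50 changed 2-fold and 40 of 50 changed 4-fold, with 11 false calls among 150. In a further draw with the same changes DESeq2 made 34 false calls beside 146 true ones for day 1, and 40 beside 157 for day 8.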

Results

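The oral siphon of Ciona robusta, the tube through which this tunicate takes in seawater, regrows after amputation, and its messenger RNA was profiled before and during that regrowth. Non-regenerating siphons and siphons 0, 1, 3 and 8 days after amputation were represented by 3 libraries each, and each library pooled the RNA of 5 siphon samples. The non-regenerating libraries held 18585176, 33413013 and 10573547 counts for replicates 1, 2 and 3. The day 0 libraries held 18531049, 21646665 and 18713760, and the day 1 libraries 16147922, 18318587 and 21005947. The day 3 libraries held 7039611, 12163241 and 14346807, and the day 8 libraries 12545397, 15170419 and 14662380. Between 15296 and 17406 of the 17745 transcripts had at least 1 count in a library. P-values measure the spread between these pools.

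The groups differed first in a few very abundant transcripts, which were singled out after their values were seen. ENSCINT00000009238 took 6.01%, 5.37% and 4.57% of all counts in the day 0 libraries. In the non-regenerating group it took 1.47% of replicate 1, but 1.59 CPM of the library total in replicate 2 and 0.568 CPM in replicate 3. ENSCINT00000019271 was the reverse, with 7.07%, 6.75% and 5.83% of the counts in the non-regenerating libraries and between 0.115% and 0.726% in the 12 libraries of days 0, 1, 3 and 8. The 20 most counted transcripts of a library together held 26.4% to 29.4% of the counts in the non-regenerating group and 16.8% to 21.96% in the others.

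**Figure D1:**
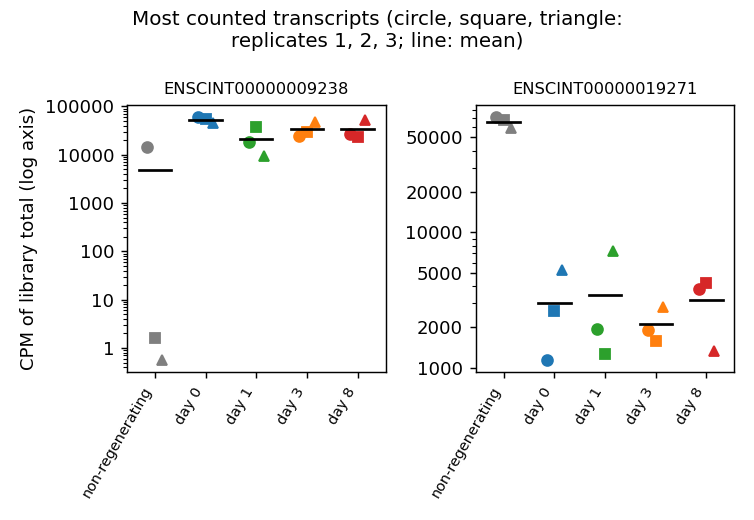
Share of ENSCINT00000009238 and ENSCINT00000019271 in each of the 15 libraries, in CPM of the library total on a log axis, by group (points are libraries, lines are group means of 3). ENSCINT00000009238 lies at 14720 CPM in non-regenerating replicate 1 and below 2 CPM in replicates 2 and 3, and ENSCINT00000019271 lies at 58300 CPM or more in the non-regenerating libraries and at 7255 CPM or less in the other 12.

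The first principal component of log2 CPM, with 41.7% of the variance, separated the non-regenerating libraries from the others, at -52, -129 and -150 against -21.6 to 58.5 for the other 12. The 3 day 0 libraries lay close together, with Spearman correlations across transcripts of 0.958 to 0.981. Those of the non-regenerating libraries were 0.885 to 0.941, and their biological coefficient of variation was 0.497, compared with 0.287 to 0.334 in the other groups. Several libraries lay nearer to another stage than to their own. The library labelled day 1 replicate 3 correlated most with day 8 replicate 2 (rho 0.975), the library labelled day 8 replicate 3 with day 1 replicate 2 (rho 0.980), day 1 replicate 2 with day 8 replicate 3, and the library labelled day 3 replicate 3 with day 0 replicate 1 (rho 0.977). Day 3 replicate 2 was also nearest to day 1 replicate 2, and non-regenerating replicate 1 to day 8 replicate 2 (rho 0.923). All libraries were kept under their labels.

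**Figure D2:**
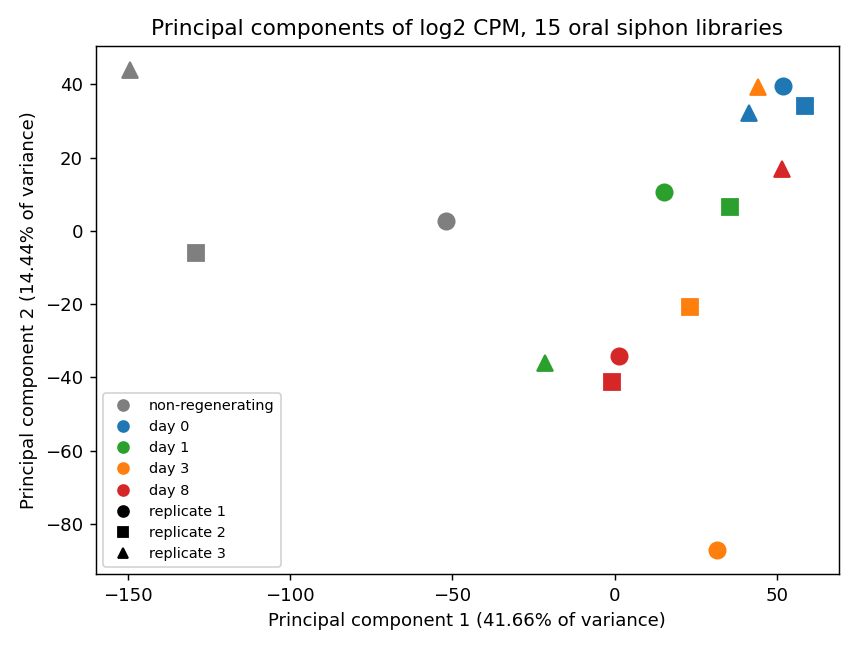
First and second principal components of log2 CPM for the 15 libraries, with 41.7% and 14.4% of the variance (colours are groups, shapes are replicate numbers, axes in component scores). The non-regenerating libraries lie between -150 and -52 on the first component, and day 3 replicate 3 lies among the day 0 libraries.

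The comparison of day 1 with day 0 asked what changed in the first day after amputation. Of 15328 transcripts, 5 passed the test, of which 3 rose and 2 fell. ENSCINT00000032868 rose from 1.71 ± 0.0776 CPM to 8.30 ± 2.11 CPM (SD, n = 3 each), a log2 fold change of 2.27 ± 0.354 (SE) with an adjusted p of 0.0489 in edgeR. ENSCINT00000026108 rose from 3.74 ± 0.969 to 12.7 ± 0.744 CPM, a log2 fold change of 1.76 ± 0.234 with an adjusted p of 0.0376 in edgeR. ENSCINT00000024202 also rose, from 23.5 ± 3.87 to 65.7 ± 11.03 CPM, a log2 fold change of 1.48 ± 0.228 with an adjusted p of 0.0489 in edgeR; it was chosen after its values were seen. ENSCINT00000002977 fell from 124 ± 15.8 to 43.5 ± 8.88 CPM, and ENSCINT00000002984 from 140 ± 15.3 to 49.9 ± 9.95 CPM. Their log2 fold changes were -1.52 ± 0.238 and -1.49 ± 0.227, both with an adjusted p of 0.0489 in edgeR. The counts of these 2 moved together over the libraries, so they may not be separate findings. In the 5 transcripts no day 1 library overlapped a day 0 library. Non-regenerating siphons lay beyond day 1 in the same direction for ENSCINT00000026108, at 25.9 ± 1.64 CPM, and for ENSCINT00000002977, at 23.3 ± 3.38 CPM, but not for ENSCINT00000024202, at 25.7 ± 5.73 CPM.

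**Figure D3:**
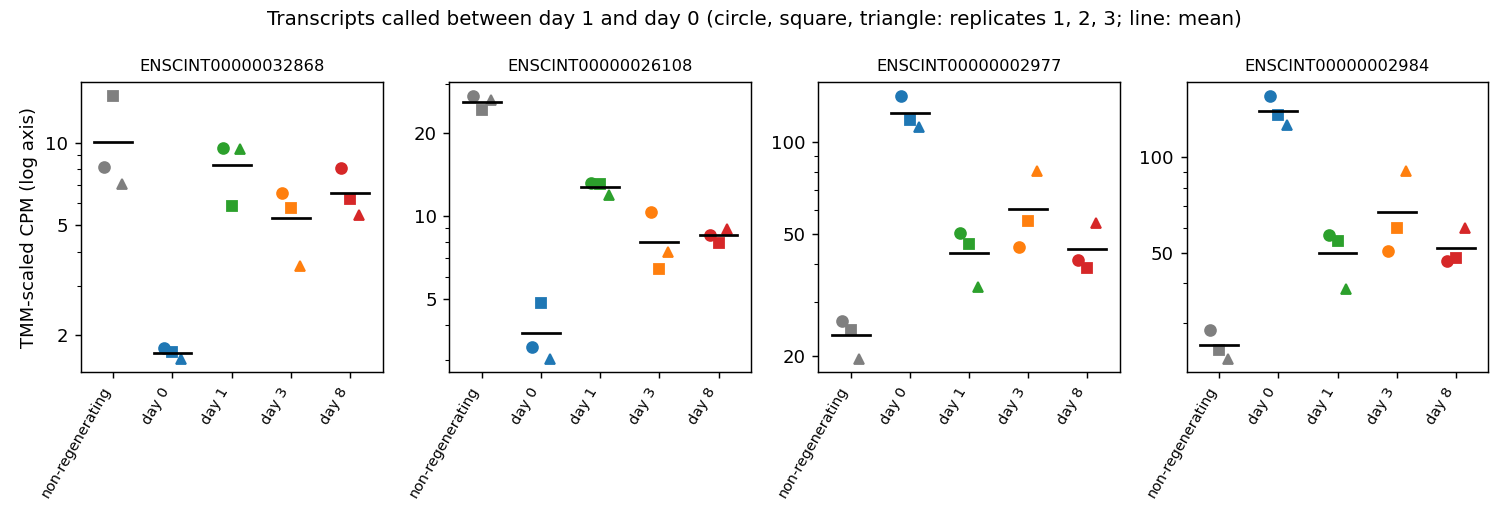
TMM-scaled CPM, on a log axis, of the 4 transcripts named by rule in the comparison of day 1 with day 0, in each of the 15 libraries by group (points are libraries, lines are means of 3). ENSCINT00000026108 has a mean of 3.74 CPM at day 0 and 12.7 CPM at day 1, and ENSCINT00000002984 one of 140 CPM at day 0 and 49.9 CPM at day 1.

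At an unadjusted p under 0.05 there were 1613 transcripts between day 1 and day 0, where 766 are expected by chance, and the groups did not overlap in 23.2% of transcripts, where chance gives 10%. Such chance values, here and below, are averages, and transcripts that move together can put a single comparison far above or below them. How far was not measured, so an excess does not by itself show a change. DESeq2 called 166 transcripts, limma voom 4 and limma voom with library weights 338. The 5 calls became 1 without day 0 replicate 2 and 0 without any other library of day 0 or day 1, 0 without replicate 3 of days 1, 3 and 8, with the replicate block or in the fit without the non-regenerating group, 164 (67 higher, 97 lower) without all libraries numbered 3, and 1, which was higher, with library totals alone, which shifted the median log2 fold change from 0.04 to 0.20. Over 21 alternatives in edgeR, DESeq2 and limma voom, ENSCINT00000032868 passed in 6 (adjusted p of 3.65e-06 to 0.282), ENSCINT00000026108 in 12 (1.16e-09 to 0.206), ENSCINT00000002977 in 7 (1.21e-05 to 0.323) and ENSCINT00000002984 in 7 (5.01e-06 to 0.265).

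At day 3, no transcript passed the test against day 0 in edgeR, in which the lowest adjusted p was 0.543. ENSCINT00000004456 had the lowest p among the higher transcripts, with 74.1 ± 13.7 CPM at day 3 and 21.6 ± 7.02 CPM at day 0. ENSCINT00000024202 stood at 56.1 ± 10.9 and 23.5 ± 3.87 CPM. Among the lower ones, ENSCINT00000002984 stood at 67.0 ± 20.8 CPM against 140 ± 15.3, and ENSCINT00000002977 at 60.4 ± 18.2 against 124 ± 15.8. These 4 were chosen after their values were seen, and their log2 fold changes were 1.78 ± 0.303, 1.25 ± 0.227, -1.06 ± 0.225 and -1.04 ± 0.236. There were 1043 transcripts at an unadjusted p under 0.05, and the groups did not overlap in 14.2% of transcripts, against 10% by chance. DESeq2 called 30 transcripts, limma voom 0 and limma voom with library weights 462. Without day 3 replicate 3 alone edgeR called 0, without replicate 3 of days 1, 3 and 8 together 259, with 136 higher and 123 lower, and without all libraries numbered 3 it called 837, with 378 higher and 459 lower; the sets of libraries were chosen after the data were seen.

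At day 8 the same 4 transcripts had the lowest p against day 0, and none passed the test in edgeR, in which the lowest adjusted p was 0.113. ENSCINT00000004456 stood at 74.7 ± 23.1 CPM and ENSCINT00000024202 at 64.0 ± 12.3 CPM, with log2 fold changes of 1.79 ± 0.303 and 1.44 ± 0.228. ENSCINT00000002984 stood at 51.7 ± 7.15 CPM and ENSCINT00000002977 at 44.9 ± 8.47 CPM, with log2 fold changes of -1.44 ± 0.227 and -1.47 ± 0.238. At an unadjusted p under 0.05 there were 2192 transcripts, where chance gives 766, and 22.3% of transcripts showed no overlap, where chance gives 10%. DESeq2 called 376, limma voom 0 and limma voom with library weights 3920. Without day 8 replicate 3 alone edgeR called 79, and without replicate 3 of days 1, 3 and 8 together it called 982, with 496 higher and 486 lower, and without all libraries numbered 3 it called 2004, with 1024 higher and 980 lower.

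The edgeR calls of days 1, 3 and 8 against day 0 had 0 transcripts in common for each pair of stages, as had 20 simulations of unchanged groups against shared controls, since day 3 and day 8 had no calls; those of DESeq2 had 20, 115 and 23 in common for days 1 and 3, days 1 and 8, and days 3 and 8. Across transcripts, which are not independent replicates, the fold changes of days 1 and 3 correlated at r = 0.712 where unchanged groups gave 0.491, those of days 1 and 8 at 0.817 where they gave 0.497, and those of days 3 and 8 at 0.734 where they gave 0.488. The covariances were 0.249, 0.343 and 0.276, compared with a simulated 0.115 for each pair, which left 0.133, 0.228 and 0.161. An exchange of the labels of day 1 replicate 3 and day 8 replicate 3, taken up below, would put a library of each day in the other group. The means of days 1 and 8 would then be more alike, so their higher values may not be a shared response. Part of the correlations comes from the shared day 0 libraries. Part of their excess can too, for transcripts in which these libraries vary more than simulated ones or share an offset. Day 0 had the lowest biological coefficient of variation of the groups (0.287), but this does not bear on an offset common to all its pools. The simulation used dispersions shared by all groups, drew each transcript by itself and held no such offset. How much of the excess comes from day 0 is therefore left open.

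Consecutive stages were compared to ask what changed within the regrowth, and 0 transcripts passed between days 1 and 3 or between days 3 and 8 in edgeR. The following were among the transcripts with the lowest p and were chosen after their values were seen. ENSCINT00000017324 stood at 158 ± 11.7 CPM at day 0, 276 ± 3.41 at day 1, 122 ± 33.2 at day 3 and 281 ± 19.1 at day 8, with log2 fold changes of -1.17 ± 0.204 (adjusted p = 0.746 in edgeR) from day 1 to day 3 and 1.20 ± 0.205 (adjusted p = 0.604 in edgeR) from day 3 to day 8. ENSCINT00000032985 stood at 9.07 ± 5.69, 4.97 ± 1.37, 18.5 ± 1.41 and 5.23 ± 2.02 CPM at days 0, 1, 3 and 8, and ENSCINT00000014408 at 209.6 ± 72.2, 115 ± 34.5, 256 ± 41.3 and 86.3 ± 14.5 CPM. The day 3 and day 0 libraries overlapped for ENSCINT00000017324 and ENSCINT00000014408. At an unadjusted p under 0.05 there were 458 transcripts between days 1 and 3 and 459 between days 3 and 8, where 766 are expected by chance, and the groups did not overlap in 9.04% and 7.93%, where chance gives 10%. DESeq2 called 11 and 18 transcripts, limma voom 0 and 0, and limma voom with library weights 1 and 28. Without all libraries numbered 3, a set chosen after the data were seen, edgeR called 93 and 46. Of these, 16 and 14 were higher and 77 and 32 lower in the later stage. Day 8 was also compared with day 1, and edgeR called 0, with 222 at an unadjusted p under 0.05, where 766 are expected by chance. Other tools were not run for it. If the labels of day 1 replicate 3 and day 8 replicate 3 were exchanged, this comparison could not show a difference between the days.

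Non-regenerating siphons and siphons taken at once after amputation differed in 4336 transcripts, 28.3% of those tested, of which 2257 were higher and 2079 lower in the non-regenerating group. Of these, 1276 differed by more than 4-fold, with 633 higher and 643 lower. ENSCINT00000004162 was higher, at 89.6 ± 47.8 CPM against 1.28 ± 1.43 at day 0 (n = 3 each), a log2 fold change of 6.11 ± 1.23 with an adjusted p of 0.00326 in edgeR; its day 0 libraries ranged from 0.335 to 2.93 CPM, and the fold change from 5.57 to 7.80 over the alternatives. ENSCINT00000001756 was also higher, at 7.07 ± 5.05 CPM, where the day 0 libraries held 3 counts together. Its log2 fold change was 6.97 ± 1.19 with an adjusted p of 0.0011 in edgeR. The ratio of the summed counts of the groups, scaled for depth, was 177, with an exact 95% counting interval of 60.2 to 863. This interval, like those below, leaves out the spread between pools. The non-regenerating libraries held 128, 282 and 9 counts. ENSCINT00000019935 was lower, at 0.848 ± 0.449 CPM against 144 ± 122, a log2 fold change of -7.48 ± 2.21 with an adjusted p of 0.0236 in edgeR, which ran from 2.54e-05 to 0.202 over 20 alternatives and passed in 15. ENSCINT00000005819 was lower, at 5.27 ± 2.32 CPM against 475 ± 370, a log2 fold change of -6.52 ± 1.58 with an adjusted p of 0.00906 in edgeR. Both lower transcripts also varied widely at day 0, where ENSCINT00000019935 ranged from 4.03 to 227 CPM and ENSCINT00000005819 from 49.6 to 726 CPM.

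The groups did not overlap in 41.9% of transcripts, where chance gives 10%. With library totals alone, which shifted the median log2 fold change from 0.0374 to -0.44, 986 transcripts were higher and 4496 lower, so that 17.99% of the calls were higher where TMM scaling gave 52.05%. The 6 libraries of these groups fitted alone gave 2776 calls, and there were 2290 higher and 2694 lower without non-regenerating replicate 1, 1687 and 1296 without non-regenerating replicate 2, and 1501 and 1427 without day 0 replicate 1. ENSCINT00000019935 missed the threshold in edgeR without non-regenerating replicate 2 (adjusted p = 0.0791), without non-regenerating replicate 3 (0.063) and without day 0 replicate 2 (0.0516).

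**Figure D4:**
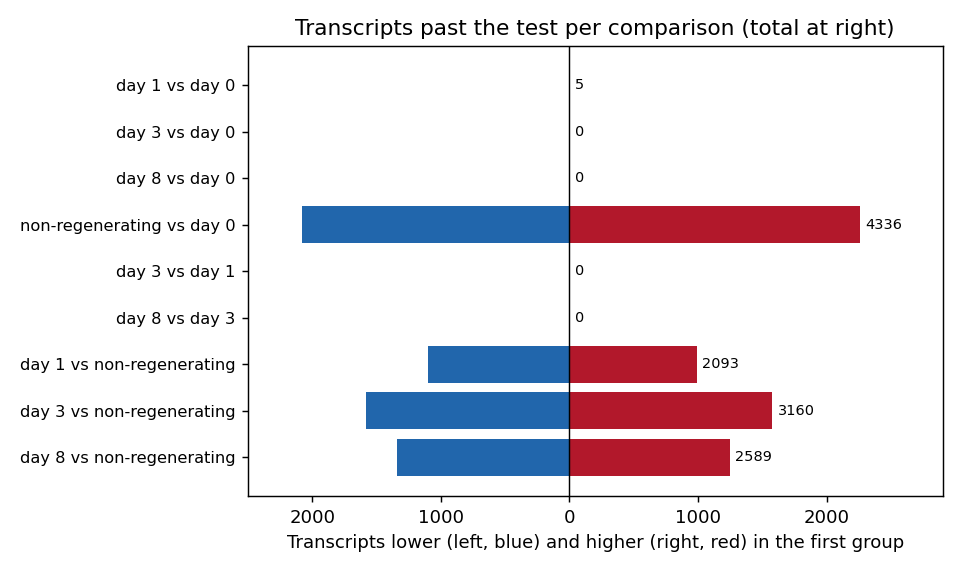
Number of transcripts past the test in each comparison of a pair of groups (edgeR, all 15 libraries), with those higher in the first-named group to the right and those lower to the left, on an axis of transcript counts. The comparisons with the non-regenerating group gave 2093 to 4336 calls, and those between pairs of days 0, 1, 3 and 8 gave 0 or 5.

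Against the non-regenerating siphons, day 1 differed in 2093 transcripts, with 991 higher and 1102 lower. ENSCINT00000013283 was higher at day 1, at 146 ± 111 CPM against 1.21 ± 0.735, a log2 fold change of 7.06 ± 1.61 with an adjusted p of 0.0116 in edgeR and 0.153 in limma voom (1.86e-06 to 0.24 over 20 alternatives). ENSCINT00000028075 was higher, at 387 ± 21.4 CPM against 9.62 ± 16.0, with an adjusted p of 0.0152 in edgeR, 0.104 in the 6 libraries alone and 0.0797 without the libraries numbered 3 (6.01e-06 to 0.104 over 20 alternatives); non-regenerating replicate 1 held 28.1 CPM and a further library 0.268 CPM. ENSCINT00000033656 was lower, at 0.309 ± 0.0769 CPM against 24.3 ± 8.14, a log2 fold change of -6.24 ± 0.811 with an adjusted p of 0.000459 in edgeR. ENSCINT00000001756 was lower, with 4 counts in the day 1 libraries together and 419 in the non-regenerating ones. Library totals alone gave 5581 calls, 92.5% of them higher, where TMM gave 47.4%. The count was 3145 (1835 higher, 1310 lower) without non-regenerating replicate 1, 1433 (613 and 820) without non-regenerating replicate 2, 1155 (538 and 617) without day 1 replicate 1, 965 (447 and 518) without day 1 replicate 2, 767 in the 6 libraries alone and 3431 with library weights.

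Day 3 differed from the non-regenerating siphons in 3160 transcripts, with 1577 higher and 1583 lower. ENSCINT00000022346 was higher at day 3, at 25.1 ± 6.48 CPM, where the non-regenerating libraries held 10 counts, all in replicate 2; the ratio was 118, with an exact 95% counting interval of 63.6 to 246. Its log2 fold change was 6.98 ± 1.27, and 6.45 to 11.67 over the alternatives, the highest without non-regenerating replicate 2, which leaves no count in that group, with an adjusted p of 0.00256 in edgeR and 0.0793 in limma voom with library weights (3.54e-10 to 0.0793 over 20 alternatives). ENSCINT00000019935 was higher, at 127 ± 186 CPM against 0.848 ± 0.449 (adjusted p = 0.0323 in edgeR, 0.000124 to 0.35 over 20 alternatives), with day 3 replicate 3 at 342 CPM and the lowest day 3 library at 18.9 CPM. ENSCINT00000015480, among the most abundant transcripts of the non-regenerating libraries, was lower, at 801 ± 514 CPM against 61130 ± 13890, a log2 fold change of -6.26 ± 0.978 with an adjusted p of 0.00099 in edgeR. ENSCINT00000001756 was lower, with 1 count in the day 3 libraries together, and the ratio of non-regenerating to day 3 was 320 with an exact 95% counting interval of 57.2 to 12700. Library totals alone gave 5643 calls, 89.4% of them higher, where TMM gave 49.9%, and the 6 libraries alone gave 1373. There were 2409 higher and 1756 lower without non-regenerating replicate 1, 1012 and 1120 without non-regenerating replicate 2, and 1133 and 1007 without day 3 replicate 2. In edgeR, ENSCINT00000019935 missed the threshold without day 3 replicate 3 (adjusted p = 0.13) and without non-regenerating replicate 1, 2 or 3 (0.0575, 0.0998 and 0.0848), and with the replicate block (0.0743).

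Day 8 differed from the non-regenerating siphons in 2589 transcripts, with 1250 higher and 1339 lower. ENSCINT00000013283 was higher at day 8, at 135 ± 77.2 CPM against 1.21 ± 0.735, a log2 fold change of 6.94 ± 1.60 with an adjusted p of 0.0112 in edgeR and 0.125 in limma voom (2.54e-06 to 0.22 over 20 alternatives). ENSCINT00000022346 was higher, at 14.4 ± 7.64 CPM against the same 10 counts, a ratio of 66.2 with an exact 95% counting interval of 35.8 to 139, with an adjusted p of 0.00573 in edgeR and 0.135 in limma voom with library weights (3.98e-08 to 0.135 over 20 alternatives). ENSCINT00000027255 was lower, at 0.626 ± 0.468 CPM against 39.4 ± 44.6 (adjusted p = 0.00516 in edgeR). Its non-regenerating libraries ranged from 6.18 to 90.1 CPM, and its log2 fold change from -6.58 to -4.44 over the alternatives, the smallest without non-regenerating replicate 2. ENSCINT00000030190 was lower, at 0.155 ± 0.136 CPM against 6.79 ± 2.97 (adjusted p = 0.00167 in edgeR). Library totals alone gave 5441 calls, 90.7% of them higher, where TMM gave 48.3%. The count was 1669 (721 higher, 948 lower) without non-regenerating replicate 2, 1586 (803 and 783) without day 8 replicate 1, 1729 (856 and 873) without day 8 replicate 2, 1638 (812 and 826) without day 8 replicate 3, 3827 (2208 and 1619) without non-regenerating replicate 1 and 927 in the 6 libraries alone.

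Of the calls against the non-regenerating group, days 1 and 3 shared 1833 in the same direction, days 1 and 8 shared 1750, and days 3 and 8 shared 2118, where 216, 177 and 267 are expected of independent lists. None went in opposite directions, which the shared non-regenerating libraries make likely. Simulated unchanged groups shared 0, but such groups have few calls to share, so this value is no yardstick. Part of the excess over independent lists can come from the shared non-regenerating libraries.

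The F-test over the 5 groups called 2379 transcripts, 15.5% of those tested, in edgeR. With the non-regenerating libraries left out of the fit, it called 0 between days 0, 1, 3 and 8, with 1549 at an unadjusted p under 0.05. Without non-regenerating replicate 2 it called 1284, with library totals alone 4290, and with DESeq2's likelihood ratio test 4498.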

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

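Limma voom with library weights, the fit without the non-regenerating group, thinning, counting near-identical transcripts once, leaving out the libraries numbered 3, and all values of the mean of days 1, 3 and 8 against day 0 were chosen after seeing the data. The direction of the named transcripts was the same in all 836 values recomputed under the alternatives. These transcripts were chosen from the same libraries by fold change and lack of overlap, or by low p. A reversal was therefore unlikely from the start, and the count is no evidence of stability. Of the 836 values, 673 stayed on their side of the threshold, 53 passed it newly and 110 no longer passed it. The counts of the non-regenerating group against day 0 ran from 2776 to 5699 over the alternatives other than leaving out single libraries. For the counts that moved by over 1.5 times, the cause was not tested. Fits of fewer libraries have fewer degrees of freedom, but this does not account for rises. Without the libraries numbered 3, day 8 against day 0 rose from 0 to 2004. The weighted fit gave replicate 3 of days 0, 1, 3 and 8 weights of 0.576, 0.484, 0.529 and 0.483. The other libraries of these days had 0.965 to 2.72, and the non-regenerating ones 0.446 to 0.865. A transcript that changed 2-fold was rarely recovered at this size and depth, 7 times in 50 in the simulation of day 1 against day 0. Estimated correlations for the gene sets, and all other alternatives for gene lists, were not run, because no identifier had a name.

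For day 1 against day 0, which called 5, library totals alone gave 1, the filter of 10 CPM 1, DESeq2 166, the replicate block 0, the 6 libraries alone 2, and leaving out 1 library 0 to 1. Library weights gave 338, the fit without the non-regenerating group 0, thinning 1, near-identical transcripts counted once 1, leaving out replicate 3 of days 1, 3 and 8 gave 0, and leaving out all libraries numbered 3 gave 164. For day 3 against day 0, which called 0, DESeq2 gave 30, the 6 libraries alone 1, leaving out 1 library 0, library weights 462, leaving out replicate 3 of days 1, 3 and 8 gave 259 and all libraries numbered 3 gave 837. For day 8 against day 0, which called 0, the same settings gave 376, 1, 0 to 79 (79 without day 8 replicate 3), 3920, 982 and 2004. With the non-regenerating group as the reference, days 1, 3 and 8 gave 2093, 3160 and 2589.

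For the non-regenerating group against day 0, which called 4336, the 6 libraries alone gave 2776 and leaving out 1 library 2928 to 4984. For day 3 against day 1, DESeq2 gave 11, library weights 1 and leaving out all libraries numbered 3 gave 93. For day 8 against day 3, these gave 18, 28 and 46, and leaving out replicate 3 of days 1, 3 and 8 gave 1.

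Against the non-regenerating group, day 1 (2093) had 5581 calls with library totals alone, 767 in the 6 libraries alone, 3431 with library weights and 3276 without the libraries numbered 3. Leaving out 1 library gave 965 (without day 1 replicate 2) to 3145 (without non-regenerating replicate 1), and 1155 without day 1 replicate 1. Day 3 (3160) had 5643 with library totals alone, 1373 in the 6 libraries alone and 2132 to 4165 without 1 library. Day 8 (2589) had 5441, 927 and 1586 (without day 8 replicate 1) to 3827 (without non-regenerating replicate 1), with 1669 without non-regenerating replicate 2 and 1638 without day 8 replicate 3.

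The F-test over all groups (2379) gave 4290 with library totals alone, 4498 with DESeq2, 4120 with library weights, 0 without the non-regenerating group, 4009 without the libraries numbered 3, and 1284 (without non-regenerating replicate 2) to 3230 without 1 library. The mean of days 1, 3 and 8 against day 0 (4) gave 451 with DESeq2, 11 with limma voom, 0 with the replicate block, 3054 with library weights, 805 without replicate 3 of days 1, 3 and 8, and 1521 without the libraries numbered 3. Leaving out 1 library gave 0 to 304: 304 without day 3 replicate 3, 14 without day 8 replicate 3, 2 without day 1 replicate 3 or day 3 replicate 1, and 0 without any day 0 library, day 1 replicate 2, day 3 replicate 2, or day 8 replicate 1 or 2.

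The calls shared by days 1 and 3, days 1 and 8, and days 3 and 8 against day 0 (0 each) were 20, 115 and 23 with DESeq2, 145, 304 and 409 with library weights, and 129, 144 and 745 without the libraries numbered 3. Days 3 and 8 shared 229 without replicate 3 of days 1, 3 and 8. With day 0 as the reference of the earlier stage and the non-regenerating group as that of the later, the pairs shared 1, 1 and 0.

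Libraries with the same replicate number did not as a rule deviate in the same direction. Of 30 such pairs, 5 had deviations from their group means that correlated at r over 0.1. The mean r of the 30 was -0.0419 where the other 60 pairs had 0.0201, and 3 of 15 libraries correlated best with their own number. These measures miss opposite deviations. Among the libraries numbered 3, r was -0.5921 for days 1 and 8, -0.3021 for days 1 and 3, and 0.3015 for days 3 and 8. The number 3 may therefore mark a structure that these measures and the block do not capture. With the block, the non-regenerating group against day 0 gave 3917 calls, days 1, 3 and 8 against the non-regenerating group 1748, 2762 and 2154, and the F-test 1845.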

Other observations

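The mean of days 1, 3 and 8 against day 0, and the tests of whether replicate 3 of day 1, day 3 and day 8 follows the difference between the non-regenerating and day 0 groups, and the test of abundant transcripts, were chosen only after the data were seen.

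Against day 0, the mean of days 1, 3 and 8 differed in 4 transcripts in edgeR, with 2275 at an unadjusted p under 0.05. ENSCINT00000024202 was higher, at 61.9 ± 10.8 CPM (SD, n = 9) against 23.5 ± 3.87 (n = 3), a log2 fold change of 1.39 ± 0.199 (SE) with an adjusted p of 0.0291 in edgeR. ENSCINT00000026108 was higher, at 9.74 ± 2.49 CPM against 3.74 ± 0.969 (adjusted p = 0.0401 in edgeR). ENSCINT00000002977 was lower, at 49.6 ± 13.6 CPM against 124 ± 15.8, and ENSCINT00000002984 at 56.2 ± 14.6 CPM against 140 ± 15.3, both with an adjusted p of 0.0189 in edgeR. As at day 1, the lower transcripts may be a single signal. In each of the 4, no library of days 1, 3 and 8 overlapped a day 0 library, but the count was 0 without any 1 of the day 0 libraries, day 1 replicate 2, day 3 replicate 2, or day 8 replicate 1 or 2, 2 without day 1 replicate 3 or day 3 replicate 1, 14 without day 8 replicate 3 and 304 without day 3 replicate 3. With a day 0 library left out, the log2 fold change of ENSCINT00000024202 was 1.289 to 1.499 and that of ENSCINT00000002984 was -1.40 to -1.24, against -1.33 with all libraries. With the replicate block all 4 missed the threshold in edgeR (adjusted p of 0.0737 to 0.121). The far higher counts with DESeq2, with library weights and without the libraries numbered 3 are given with the alternatives above.

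The comparisons of the non-regenerating siphons with days 0, 1, 3 and 8 had 1529 called transcripts in common, of which 815 were higher and 714 lower in the non-regenerating group than in each of the 4 days. Of the 5 transcripts called between days 1 and 0, 4 were also called in the same direction between the non-regenerating group and day 0, where 0.713 are expected of independent lists that do not share day 0. Across transcripts, which are not independent replicates, the fold changes of days 1, 3 and 8 against day 0 correlated with those of the non-regenerating group at r = 0.635, 0.445 and 0.559, where simulated unchanged groups gave 0.494, 0.480 and 0.492. Their covariances exceeded the simulated ones by 0.368, 0.189 and 0.343. For day 3 the measures differ, since its correlation was below the simulated one. Its share of transcripts with the same sign was 65.6%, where simulated groups gave 66.2%. Whether day 3 shares the non-regenerating difference beyond the common day 0 libraries is left open.

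The libraries labelled replicate 3 of day 1, day 3 and day 8 lay apart from the other libraries of their day. Library depth is argued against, since after thinning to the smallest total 3 of the 3 were still nearest to a library of another day. A shift in tissue share along the difference between the non-regenerating and day 0 groups stays open for each: the deviations of replicate 3 from replicates 1 and 2 correlated with that difference across transcripts at r = 0.487 for day 1, -0.21 for day 3 and -0.477 for day 8, where replicate 1 minus replicate 2 gave 0.245, -0.0303 and -0.033. An exchange of the labels of day 1 replicate 3 and day 8 replicate 3 is a candidate explanation for those libraries. With the difference between the non-regenerating and day 0 groups taken out, each still correlated better with replicates 1 and 2 of the other day. The differences in mean r were 0.491 and 0.367 (SD 0.016 and 0.0178 over 100 random draws of transcripts, not over libraries). The exchange was proposed from correlations of the same profiles, where the differences were 0.602 and 0.444, so this is no independent support. Pools that deviate in opposite directions could give the same values. Differences between the pools of animals stay open, as untested. An exchange of day 0 replicate 3 and day 3 replicate 3 was not tested. Day 3 replicate 3 lay nearest to day 0 replicate 1 (rho 0.977), but so did day 0 replicate 3 (rho 0.964).

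The non-regenerating and day 0 siphons differed in 4336 transcripts. Depth is argued against as the whole cause, since with every library thinned to the smallest total 4013 passed. The weight of a few abundant transcripts shifts all others by a common factor, which moves the balance of calls, but it is argued against as the whole cause: calls over 4-fold went both ways, 633 higher and 643 lower with TMM, and 379 higher and 1259 lower with library totals alone. This test replaced the one set first, which left the 20 highest out of the library sizes and decides nothing, since it moved the count only to 4338. A difference between the siphons themselves, which the labels name, stays open as a hypothesis, and so do differences in handling or housing, which the labels do not give.

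On the first principal component, non-regenerating replicate 1 lay between replicates 2 and 3 of its group and day 0. Its mean rho was lower with day 0 (0.885) than with days 1, 3 and 8 (0.911, 0.902 and 0.913). Only a share of day 0 tissue was tested, and not one of the later days. A share of day 0 tissue in that pool could raise all transcripts abundant at day 0 alike, but 8 transcripts had at least 50 CPM in every day 0 library and at most 1 CPM in non-regenerating replicates 2 and 3. Their level was 18.2% of the day 0 mean at the median, with quartiles of 13.5% and 32.4%, a spread of 2.4 where the day 0 libraries reached 2.52, so an admixture and a pool of another state cannot be told apart with so few transcripts. No biological explanation was tested.

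Other splits of the same libraries were counted for each comparison, all of them for pairs of groups and a random draw for the 2 larger comparisons. A comparison of 3 libraries with 3 has 10 splits, too few for a share under 0.05. The real split and the highest other gave 5 and 0 calls for day 1 against day 0, 0 and 20 for day 3 against day 0, 0 and 0 for day 8 against day 0, and 4336 and 0 for the non-regenerating group against day 0. They gave 0 and 0 for day 3 against day 1 and for day 8 against day 3, and 2093 and 2, 3160 and 0, and 2589 and 0 for days 1, 3 and 8 against the non-regenerating group. As many calls as in the real split came in 1 of 10 splits for day 1 against day 0 and for the 4 comparisons with the non-regenerating group, and in 10 of 10 where the real split had 0. The split of days 3 and 0 with 20 calls put day 0 replicate 3 with day 3 replicates 1 and 2, which points to a structure of the samples. For the mean of days 1, 3 and 8 against day 0, 1 of 40 splits gave 4 calls, the real one, and the highest other 0; for the F-test, 1 of 40 gave 2379, the real one, and the highest other 2. For the F-test this share is under 0.05, which argues against chance but does not exclude it, since 1 of 40 is the lowest share possible here. Random splits also mix the non-regenerating libraries with the others, which leaves few calls to be found. With the non-regenerating libraries left out the F-test called no transcript, so its result does not bear on days 0, 1, 3 and 8 alone. The mean of days 1, 3 and 8 was compared only after the data were seen, and any count above 0 would have given the same 1 of 40, so its 4 calls are left open.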
